A study of Gallus gallus with 12 samples.

How the data were processed

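RNA was measured in pooled maxillary prominences of chicken embryos, 12 arrays in 4 groups of 3, on a 1-colour Affymetrix chicken array with biotin label. Per the labels, 500 ng of total RNA per pool went through a two-cycle labelling protocol, and 1 array was hybridised per pool. The deposited values are probe set intensity on a linear scale, none of them negative. Their mean without the highest and lowest 2% of probe sets was 150.03 on every array, while their quantiles differed between arrays, so the deposited intensities had been scaled to a common trimmed mean and not quantile normalised. The summarization software and any background step are not given in the sources used here. A scaling of this kind fixes the mean of each array, so a shift of many probe sets one way in 1 group moves the rest the other way. Two-cycle labelling copies from the 3' end, so intensities also follow how complete the RNA was, and this was followed with the 5' over 3' ratios of the control probe sets.

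The table held 38535 probe sets, of which 96 were hybridisation and labelling controls, 57 were reporter gene controls and 689 were named by an accession outside the chicken series, mostly of avian viruses. These were left out of the comparisons. The virus probe sets were taken as a measure of background, and their 95th percentile on an array was the level above which a signal was called present for lower limits of fold changes. Among the 37693 chicken probe sets, 27166 carried 1 gene symbol, 177 several and 10350 none. Kept for testing were the 21354 chicken probe sets above the median of their own array (the 50th percentile) on at least 3 of the 12 arrays, 16266 of them with 1 symbol, and these stood for 10158 genes. Gene symbols were those of the probe annotation; 16122 kept probe sets had a gene identifier in the RefSeq gene table and 0 of these changed symbol. Genome positions of the probe sets were not used here.

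Intensities were analysed as log2(value + 16). A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the 4 groups shared 1 estimate of the spread per probe set. Tests were two-sided, and a probe set was called changed at a Benjamini-Hochberg adjusted p below 0.05 over the 21354 probe sets. The comparisons were each treated group against Tris+DMSO, Noggin+RA against Tris+RA and against Noggin+DMSO, the interaction (the RA effect with Noggin minus the RA effect without), and the average effects of RA and of Noggin over both states of the other factor. Fold changes are ratios on the scale of value + 16, given with the standard error (SE) of their log2 value, and group values are mean ± SD of the deposited intensity over 3 arrays. Where a group on the lower side of a comparison had at most 1 of its 3 arrays above the background level, values of that side below the level were raised to it and the fold is given as a lower limit ("at least"). This limit was at first kept for groups with 0 such arrays and was widened after seeing the data. The number of arrays limits the precision.

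Genes were named by a rule fixed before the data were examined, as were the tests and gene lists: among called probe sets with exactly 1 symbol that were the brightest of their gene and, in pairwise comparisons, whose 3 values in 1 group did not overlap the 3 of the other, the 12 largest rises and 12 largest falls for comparisons against Tris+DMSO and the 6 and 6 largest for the others. Symbols that were only accessions or open reading frame codes were skipped, and any member of a fixed list could be named as well. Because of that rule, every gene named from a pairwise comparison as changed, unless it is named as a list member, moved its way in 3 of 3 arrays against 3 of 3.

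The 21 gene lists, written from general knowledge, were 12 pathway or patterning lists and 9 lists of markers of other cell types. The first kind covered BMP signalling targets, BMP ligands with receptors and antagonists, retinoic acid targets and metabolism, HOX genes, the hedgehog, FGF and WNT pathways, frontonasal patterning factors, maxillary and first arch patterning factors, cartilage and bone, cell cycle, and apoptosis with p53 targets. The second kind covered surface epithelium, skeletal muscle, endothelium, red blood cells, white blood cells, neurons and cranial ganglia, neural crest glia, lens, and retina with pigment epithelium. PAX6, PAX7 and TFAP2B were each on both a frontonasal and a cell type list, and no measured red blood cell gene was on another list. Each list was tested in each comparison with camera of limma on 1 probe set per gene, the brightest, with a preset correlation between genes of 0.01, and adjusted over the 21 lists. The same test with a correlation estimated from the data kept 1 of the 35 list calls, the retinoic acid list in the average effect of RA (adjusted p = 0.0465). In each of the 35 calls the median and the mean of the list had the sign of the test, and the median kept its sign in all 35 after quantile normalization and after median centring. Members were also counted at an adjusted p below 0.05 adjusted over the list alone.

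Array measures were compared between the 6 Noggin and 6 Tris arrays with an exact two-sided permutation test over all 924 splits. The analysis was tested on simulated data with 200 changed probe sets in each of 10 simulations. The noise was normal, with the spread estimated for each probe set, and drawn independently between probe sets and arrays. For Noggin+DMSO against Tris+DMSO, 27.0% of 1.5-fold, 78.7% of 2-fold and 97.9% of 3-fold changes were recovered, and 5.71% of calls were false. For Tris+RA against Tris+DMSO these were 22.5%, 80.7% and 95.8%, with 5.02% false, and for the interaction 2.99%, 39.6% and 84.7%, with 5.8% false. These shares are averages over random probe sets with 200 changed at once. They need not hold for probe sets with a wider spread or where fewer change. The list test called 10 of 10 lists of 15 genes shifted by 0.5 on the log2 scale and 1 of 200 lists left alone. These lists were random probe sets with independent noise, so this count does not cover lists whose genes move together.

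Alternatives were quantile normalization, median centring, no filter, a filter at the 70th percentile, a trended and robust prior, array weights, a block for the replicate number, pseudocounts of 1 and 64, a fit of only the groups compared, a minimum fold of 1.5, an adjusted p below 0.10, and leaving out each array in turn. Added after seeing the data were a fit without both arrays at the ends of the first principal component and fits with a red blood cell level (mean log2 value of SLC4A1, HEMGN and TAL1) or the GAPDH 5' over 3' ratio as a covariate. These 3 genes are the ones of 8 measured on the red blood cell list that rose in the average effect of Noggin, so this covariate carries part of the contrast it was fitted beside. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.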

Results

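The maxillary prominence, the facial bud that forms the side of the upper beak, was profiled in chicken embryos after bead implants. At Hamburger-Hamilton stage 15 (25 somites), 2 beads were placed into the side of the head, in the region from which the bud grows. The larger bead (200 µm) carried Noggin, a secreted protein that binds BMP ligands and blocks their signalling, or the buffer Tris. The smaller bead (100 µm) carried retinoic acid (RA), the vitamin A derivative that activates nuclear retinoic acid receptors, or its solvent DMSO. Both factors were soaked in at 1 mg/ml. After 16 h at 38 °C, at stage 18, prominences were collected in pools of 12 to 15. The groups Tris+DMSO (the control), Noggin+DMSO, Tris+RA and Noggin+RA had 3 pools each, and each pool was measured on its own array. The series concerned genes that specify the midline of the face. Beads with Noggin and RA together are known to give maxillary tissue a frontonasal identity.

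The highest intensity of an array lay between 6300.0 and 8307. The mean share of chicken probe sets above background was 52.3% in Tris+DMSO, 51.1% in Noggin+DMSO, 52.4% in Tris+RA and 50.7% in Noggin+RA. Across probe sets, log2 values of 2 arrays correlated at 0.971 to 0.980 within a group (12 pairs) and 0.945 to 0.977 between groups (54 pairs). Arrays from Noggin and Tris beads also differed in measures of RNA quality and background. The ratio of 5' to 3' signal of the GAPDH control, which falls with RNA integrity and label length, was 0.695 ± 0.0409 (SD, n = 6) with Noggin and 0.815 ± 0.0266 with Tris. The exact permutation p was 0.00216, the smallest this test can give (adjusted p = 0.00432 over 6 array measures). Median intensity was 42.8 ± 2.47 with Noggin and 37.1 ± 2.13 with Tris, and the median of the virus probe sets 6.36 ± 0.883 and 4.87 ± 0.457, both with adjusted p = 0.00432 by the exact test. The EF1A ratio was 0.582 ± 0.056 and 0.654 ± 0.0308 (exact permutation p = 0.0281, adjusted 0.0337), and the actin ratio 0.498 and 0.533 (exact permutation p = 0.182, adjusted 0.182). The mean of the 8 measured red blood cell genes, as log2 deviation from the mean of the arrays, was 0.287 ± 0.255 with Noggin and -0.287 ± 0.400 with Tris (exact permutation p = 0.0108, adjusted 0.0162).

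**Figure D1:**
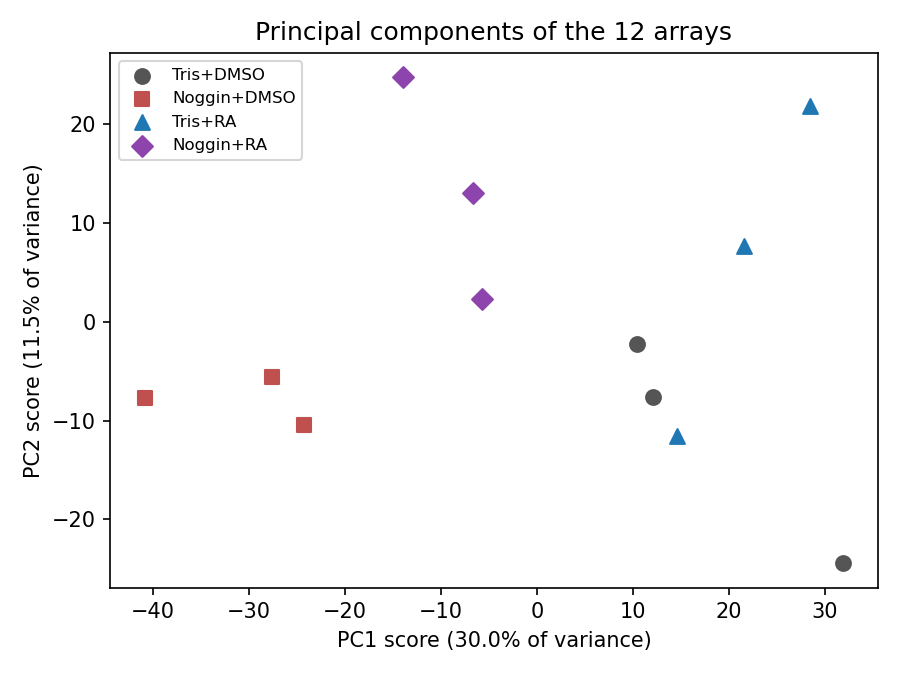
Scores of the 12 arrays on the first and second principal components of the kept probe sets, 1 point per array, axes in score units with their share of variance (30.0% and 11.5%). The 6 Noggin arrays had scores from -40.8 to -5.75 and the 6 Tris arrays from 10.5 to 31.9 on the first component. Its ends were Noggin+DMSO replicate 3 (median intensity 47.4) and Tris+DMSO replicate 1 (33.9). Within Tris+DMSO, Tris+RA and Noggin+DMSO the score fell as the median intensity rose, while Noggin+RA replicates 1 and 2 went the other way. The component thus does not set Noggin apart from array intensity.

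The first comparison asked what both factors together changed in the maxillary prominence. Noggin+RA against Tris+DMSO raised PLAU, the secreted protease urokinase, 6.72-fold (log2 2.75, SE 0.251, adjusted p = 0.00124), from 119 ± 26.2 to 919.6 ± 344. It raised DHRS3, a reductase that turns retinaldehyde back into retinol, 5.29-fold (SE 0.314 on log2, adjusted p = 0.00941). TBX22, a T-box factor required for palate formation, rose 4.31-fold (SE 0.187, adjusted p = 0.00124). LHX8, a LIM homeobox gene of the maxillary mesenchyme, was 4.33-fold lower (log2 -2.12, SE 0.359, adjusted p = 0.0238), at 631 ± 257 in the control and 131 ± 50.1 with both factors. In all, 173 probe sets changed, 109 up and 64 down and 74 of them at least 2-fold. They stood for 119 genes, with 40 more probe sets that had no symbol.

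Among the other named rises were EMX2, a homeobox factor (at least 3.63-fold), and CDC42EP3, an effector of the small GTPase CDC42 (4.54-fold). TFPI2, a serine protease inhibitor, rose 4.07-fold, PENK, the precursor of enkephalins, 4.07-fold (581 ± 113 to 2462 ± 737), and CMBL, a hydrolase, 3.04-fold. RSPO3, a secreted enhancer of WNT signalling, rose 3.22-fold from 322 ± 82.4 to 1079 ± 299.8. SFRP4, a secreted frizzled-related protein, rose 2.86-fold by the brighter of its 2 probe sets. GEM, a GTP-binding inhibitor of voltage-gated calcium channels, was at least 2.55-fold higher (14.2 against 123), and HIC1, a zinc finger repressor, at least 1.3-fold higher. MAB21L1 and MAB21L2, relatives needed for eye formation, were at least 2.83-fold and 2.70-fold lower. SOCS2, a suppressor of cytokine signalling, was 2.996-fold lower, HDAC9, a histone deacetylase, 2.89-fold and MECOM, a zinc finger factor, 2.33-fold. CYTL1, a secreted protein of cartilage, was 2.28-fold lower (2024 ± 202 to 887 ± 181). ANGPT2, a ligand of the vessel receptor TIE2, was 2.27-fold lower, SLITRK4, a neuronal membrane protein, 2.24-fold, and LMCD1, a LIM domain protein, 2.19-fold. HSPH1, a heat shock protein, was 2.14-fold lower and FAM150B, a secreted kinase ligand, at least 1.62-fold. Adjusted p over these 24 genes ran from 0.00124 to 0.0499.

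By list, the retinoic acid genes were higher in Noggin+RA (median log2 0.534 over 16 genes, camera adjusted p = 5.11e-05; adjusted p = 0.162 with an estimated correlation). DHRS3, TGM2 (transglutaminase 2, 2.08-fold) and the receptor gene RARB (1.69-fold) rose and 0 fell, with 9 rises and 1 fall adjusted over the list alone. BMP signalling targets were lower (median of 14 genes -0.291, adjusted p = 0.00727; adjusted p = 0.544 with an estimated correlation). Of these ATOH8, a bHLH factor, fell (log2 -0.73), with 3 falls adjusted over the list alone. Cell cycle genes were slightly lower (median of 21 genes -0.113, adjusted p = 0.0142), with a median of -0.0918 after quantile normalization and -0.178 after median centring. Red blood cell genes (median of 8 genes 0.47, adjusted p = 0.0129) and surface epithelium genes (median of 10 genes 0.277, adjusted p = 0.0372) were higher. In these 3 lists 0 members passed the test, 0 adjusted over the list alone, and each list had an adjusted p = 0.544 with an estimated correlation. Maxillary and first arch factors went both ways (camera adjusted p = 0.287 over 20 genes). TBX22 rose and LHX8, DLX1 and PRRX1, homeobox genes of the arch mesenchyme, fell, with 3 rises and 6 falls adjusted over the list alone. Of 11 frontonasal patterning factors 0 passed the test (camera adjusted p = 0.958). ALX1, a homeobox gene of the frontonasal mesenchyme, was at 348 ± 71.4 and 999.9 ± 340.2 (adjusted p = 0.0574) and was the 1 that passed adjusted over the list alone.

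At the level of probe sets, 19.8% had 3 values in 1 group that did not overlap the other 3, where chance gives 10%. Rises made up 63.0% of calls here, 56.4% after quantile normalization and 49.1% after median centring. Counts under other settings ran from 2 with the GAPDH ratio as a covariate (TBX22 and HTRA3, a secreted protease) and 4 with only the groups compared (DHRS3, PLAU, SPON2, a matrix protein, and 1 without a symbol), each chosen after their values were seen, to 422 at an adjusted p below 0.10. The number of calls fell to 33 without Tris+DMSO replicate 2, 35 without Noggin+RA replicate 3, 85 without Tris+DMSO replicate 1, 97 without Tris+DMSO replicate 3 and 109 without Noggin+RA replicate 1. Of the 24 named genes, 9 kept their call whichever single array was left out: CDC42EP3, CYTL1, DHRS3, EMX2, GEM, PLAU, RSPO3, SLITRK4 and TBX22. Among the lists, that of BMP targets lost its call without Noggin+RA replicate 3 (adjusted p = 0.0549, median -0.179) and had a median of -0.459 without Noggin+RA replicate 2 and of -0.125 without the filter (adjusted p = 0.0248). That of cell cycle genes lost it without Noggin+RA replicate 3 (0.33, median -0.0647) or Tris+DMSO replicate 1 (0.0784), and that of red blood cells without Noggin+RA replicate 1 (0.069) or Tris+DMSO replicate 3 (0.353, median 0.169). That of surface epithelium lost it without Noggin+RA replicate 1 (0.0507) or 3 (0.195) or Tris+DMSO replicate 1 (0.119) or 3 (0.0626).

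**Figure D2:**
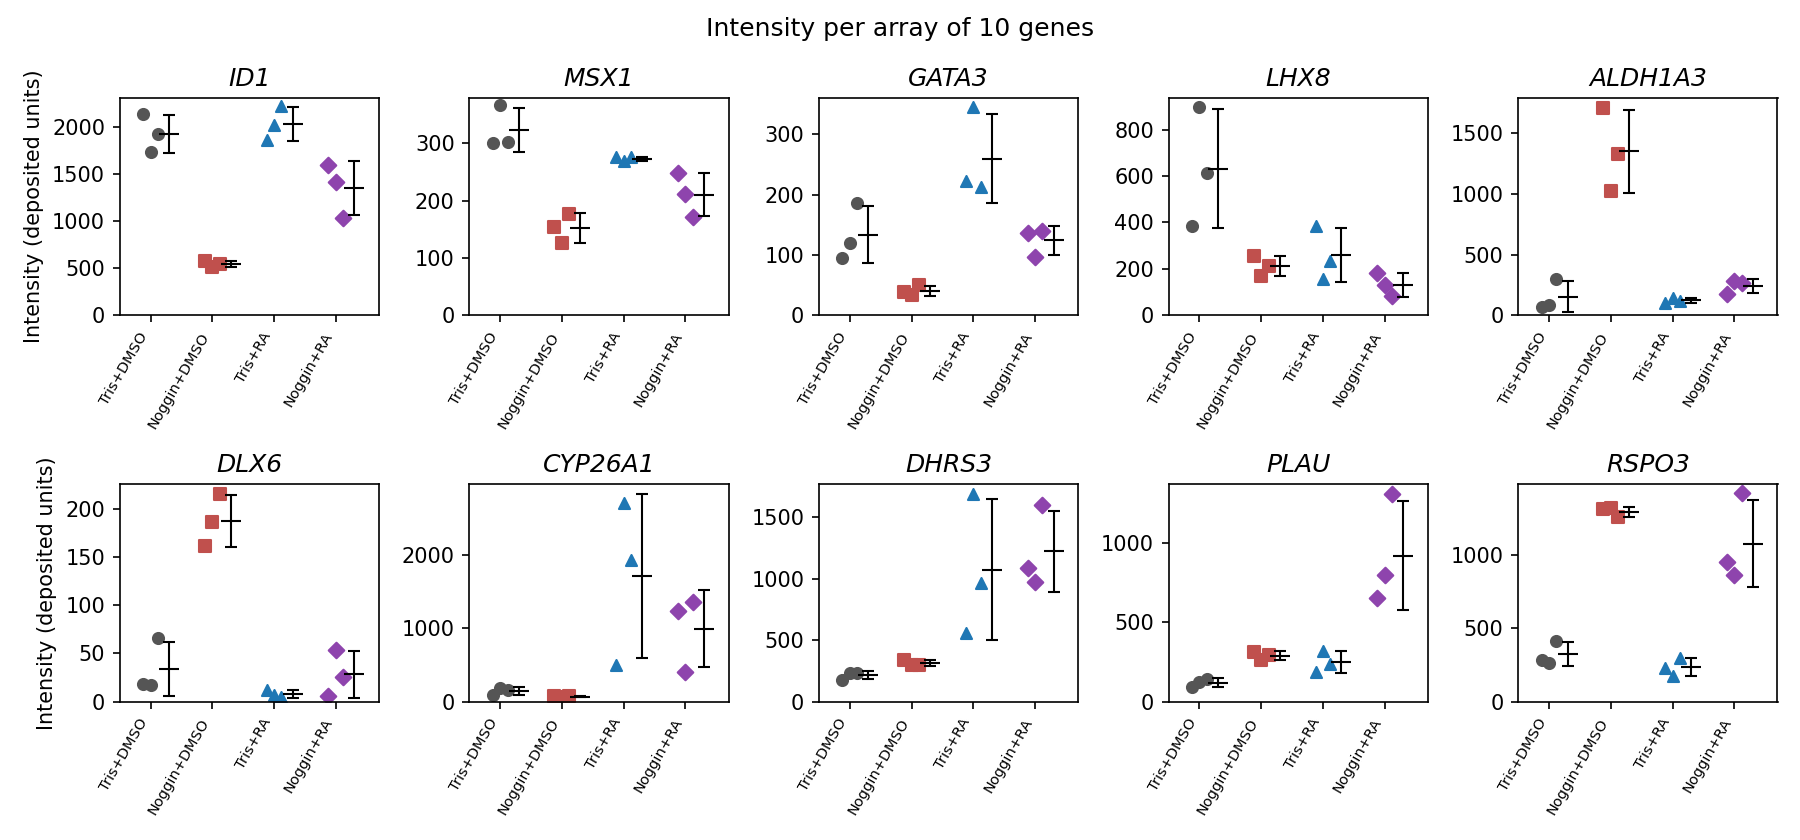
Deposited intensity (linear axis from 0) of 10 genes on each array, points for the 3 arrays of each group and bars for mean ± SD. ID1, MSX1 and GATA3 had their lowest mean in Noggin+DMSO, ALDH1A3 and DLX6 their highest mean there, CYP26A1 and DHRS3 higher means in both groups with RA than in those without, and PLAU its highest mean in Noggin+RA (919.6 against 119 in the control).

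RA alone was compared with the control to separate its effect from that of Noggin. With limma, 0 probe sets passed the test, and 1368 had an unadjusted p below 0.05 where chance gives 1068. The share of probe sets with values that did not overlap was 10.4%, where chance gives 10%. CYP26A1, the main enzyme that degrades RA and a gene that RA is known to induce, was at 146 ± 51.1 in the control and 1717 ± 1118 with RA (log2 3.17, SE 0.570, adjusted p = 0.155). DHRS3 was at 214 ± 31.3 and 1072 ± 573 (log2 2.11, SE 0.314, adjusted p = 0.119). PENK had the smallest adjusted p of any gene, 0.0557, at 581 ± 113 and 2842 ± 962 (4.64-fold, SE 0.281 on log2), shared with 1 probe set without a symbol (log2 -1.43). CYP26A1, DHRS3 and PENK each had an SE above the median of 0.156 over probe sets. That 0 passed therefore does not mean that RA alone changed no gene.

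By list, 8 of 21 passed the test for RA alone, and 0 of them kept the call with an estimated correlation. The retinoic acid list was higher (median of 16 genes 0.254, adjusted p = 6.09e-06; adjusted p = 0.103 with an estimated correlation). It had 6 rises adjusted over the list alone, among them CYP26A1, CYP26B1, ALDH1A2 and RARB, and 0 over all probe sets. HOX genes, which pattern the hindbrain and the arches behind the jaw, were also higher (median of 5 genes 0.466, adjusted p = 0.00854; adjusted p = 0.187 with an estimated correlation). On the arrays the list mean was -0.267, 0.617 and 0.520 with RA and -0.555 to -0.273 in the control, so Tris+RA replicate 1 lay level with the control, and without it the median was 0.965. The same array was the lowest of the 3 on the retinoic acid list (-0.0687 beside 0.421 and 0.299). Of 16 HOX genes on the array 5 passed the filter, and without the filter the call was lost (median 0.0392, adjusted p = 0.149). HOXA3 and HOXB1 passed adjusted over the list alone, and HOXB1 was at 41.2 ± 11.8 in the control and 141 ± 89.3 with RA. Maxillary and first arch factors were lower (median of 20 genes -0.264, adjusted p = 0.00854; adjusted p = 0.187 with an estimated correlation). Adjusted over the list alone LHX8, BARX1, TWIST2, NKX3-2, DLX1 and DLX5 fell and PITX1 rose, and 0 passed over all probe sets. Skeletal muscle genes were higher (median of 12 genes 0.232, adjusted p = 0.0165; adjusted p = 0.151 with an estimated correlation), with MYL4 and TNNC1 past the test adjusted over the list alone. BMP targets were higher (median of 14 genes 0.108, adjusted p = 0.0215; adjusted p = 0.36 with an estimated correlation), with BAMBI and GATA3 past the test adjusted over the list alone. Red blood cell genes were higher (median of 8 genes 0.271, adjusted p = 0.0396; adjusted p = 0.573 with an estimated correlation), with 0 past either test. Cartilage and bone genes were lower (median of 12 genes -0.191, adjusted p = 0.0353; adjusted p = 0.187 with an estimated correlation), with 1 up and 2 down adjusted over the list alone. Genes of retina and pigment epithelium were lower (median of 9 genes -0.103, adjusted p = 0.0429; adjusted p = 0.329 with an estimated correlation), with OTX2 and MITF past the test adjusted over the list alone.

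Without Tris+RA replicate 1 the count of changed probe sets for RA alone was 21, and under other settings that left out no array it ran up to 10 (with 64 added before log2). Without the filter the lists of cartilage and bone (median -0.0642), red blood cells (0.228) and retina (-0.00699) also lost their call, each with an adjusted p = 0.149, as did that of muscle (0.122, adjusted p = 0.177). With the mean of all probe sets of a gene that of cartilage and bone lost it too (median -0.125, adjusted p = 0.106). Without both arrays at the ends of the first principal component, chosen after seeing the data, the medians of muscle and red blood cells were 0.138 (adjusted p = 0.0152) and 0.455 (0.00318). The list of BMP targets lost its call without Tris+RA replicate 2 (adjusted p = 0.102) or Tris+DMSO replicate 2 (0.0551). Those of maxillary factors (0.0644) and muscle (0.101) lost it without Tris+DMSO replicate 3. The median of maxillary factors was -0.167 without Tris+RA replicate 1 and -0.154 without Tris+DMSO replicate 2, and that of muscle 0.054 without Tris+RA replicate 1 and 0.138 without Tris+DMSO replicate 1. That of cartilage and bone lost it without Tris+RA replicate 2 (0.131) or Tris+DMSO replicate 1 (0.0593), 2 (0.0716) or 3 (0.0644). That of retina lost it without Tris+RA replicate 1 (0.326) or Tris+DMSO replicate 1 (0.112) or 3 (0.163, median -0.265), and its median was -0.0658 without Tris+RA replicate 2, -0.167 without Tris+RA replicate 3 and -0.0195 without Tris+DMSO replicate 2. That of red blood cells lost it without Tris+RA replicate 1 (0.425, median 0.156) or 3 (0.0693) or Tris+DMSO replicate 3 (0.837, median -0.0265), and its median was 0.455 without Tris+DMSO replicate 1.

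Noggin alone was compared with the control to show the effect of blocked BMP signalling. ID1, an inhibitor of bHLH factors and a direct target of BMP signalling, was 3.46-fold lower (log2 -1.79, SE 0.154, adjusted p = 0.000592), at 1933 ± 202 in the control and 545 ± 32.5 with Noggin. ALDH1A3, an enzyme that makes RA from retinaldehyde, rose 9.54-fold (SE 0.403 on log2, adjusted p = 0.00249), from 152 ± 128 to 1353 ± 342. FOXD1, a forkhead gene on the hedgehog list, rose 4.22-fold (SE 0.250, adjusted p = 0.0024), from 424 ± 180 to 1746 ± 52.4. PRRX1 was 3.22-fold lower (SE 0.193, adjusted p = 0.00218), at 1342 ± 334 and 400.5 ± 50.8. In all, 1058 probe sets changed, 634 up and 424 down and 244 of them at least 2-fold. They stood for 754 genes, with 231 more probe sets that had no symbol.

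SLC4A1 (band 3) and ANK1, proteins of the red cell membrane, rose 6.20-fold and 3.99-fold, and TUBB1, a tubulin of thrombocytes, 4.05-fold. ANK1 was called in 1 of its 3 probe sets and went the other way in 1. PTGDS, a prostaglandin D synthase, rose at least 4.26-fold (23.4 ± 16.9 to 214 ± 66.9) and SCARA5, a ferritin receptor, at least 4.20-fold. DLX6, a distal-less homeobox gene of the first arch, rose at least 3.43-fold (33.7 ± 27.8 to 188 ± 26.8), and RSPO3 3.95-fold (322 ± 82.4 to 1297 ± 34.4). HTR1E, a serotonin receptor, rose 3.98-fold and DIO2, the deiodinase that activates thyroid hormone, at least 3.28-fold, and GEM was at least 2.67-fold higher. ITGA4, an integrin chain, was 3.37-fold lower, HSPH1 2.90-fold, LHX8 2.70-fold and TCF21, a bHLH factor of head muscle precursors, at least 2.47-fold. MECOM was 2.66-fold lower, SOHO1, a homeobox gene of sensory organs, 2.63-fold, WIF1, a secreted WNT inhibitor, at least 2.24-fold, and GATA3, a zinc finger factor, at least 2.41-fold. SCNM1, a splicing factor, was at least 2.63-fold lower and PCDH10, a protocadherin, at least 1.99-fold. Adjusted p over the 24 named genes ran from 0.000592 to 0.0485.

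BMP signalling targets fell as a group in Noggin+DMSO (median of 14 genes -0.928, camera adjusted p = 1.88e-06; adjusted p = 0.283 with an estimated correlation). ID1, GATA3, ID2, MSX1, ID3, ATOH8 and SMAD6 fell and 0 rose, with 10 falls adjusted over the list alone. MSX1, a homeobox gene induced by BMP, was 2.02-fold lower (323 ± 38.1 to 153 ± 25.8), and SMAD6, an inhibitor in the BMP pathway, 1.78-fold lower. ID2 was 2.38-fold lower in its brightest probe set, was called in 2 of its 4, and went the other way in 1. Maxillary and first arch factors moved both ways (camera adjusted p = 0.875 over 20 genes). DLX6, NKX3-2, TBX22, DLX5 and LHX9 rose and PRRX1, LHX8, PRRX2 and DLX1 fell, with 7 rises and 5 falls adjusted over the list alone. DLX5 rose 2.52-fold from 758 ± 124 to 1921 ± 133, and NKX3-2, a homeobox gene of the jaw joint, 3.20-fold. Of the hedgehog list (camera adjusted p = 0.525 over 12 genes), FOXD1 and HHIP, a hedgehog-binding inhibitor (2.31-fold), rose, with 3 rises adjusted over the list alone.

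Other cell types and RNA quality moved with Noggin too. Red blood cell genes were higher by a median of 0.697 over 8 genes (camera adjusted p = 0.00309; adjusted p = 0.619 with an estimated correlation). SLC4A1 and TAL1, an erythroid and endothelial factor, rose, with 5 rises adjusted over the list alone. The globin genes HBBR and HBAD were at 3342 ± 1313 and 3676 ± 1199 in the control and 5200 ± 484 and 5665 ± 747 with Noggin. White blood cell genes were higher by a median of 0.417 over 9 genes (adjusted p = 0.024; adjusted p = 0.619 with an estimated correlation). CD74, the invariant chain of MHC class II, was the 1 that rose over all probe sets and over the list alone. Cell cycle genes were lower (median of 21 genes -0.212, adjusted p = 0.00181; adjusted p = 0.619 with an estimated correlation), with 0 past the test and 0 adjusted over the list alone. Their median was -0.156 after quantile normalization and -0.32 after median centring. The mean GAPDH ratio was 0.824 in the control and 0.669 with Noggin, beside each of these gene groups.

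Non-overlapping values were seen for 29.8% of probe sets, where chance gives 10%. Quantile normalization and median centring moved the median of all probe sets by -0.105 and -0.109, so rises and falls are relative to that shift. Rises made up 59.9% of calls here, 44.4% after quantile normalization and 30.4% after median centring. With the GAPDH ratio as a covariate, chosen after seeing the data, 0 probe sets passed in limma: the median size of the log2 change of the 1058 went from 0.713 to 0.675 and its median SE from 0.147 to 0.352. With the mean of SLC4A1, HEMGN and TAL1 as a covariate 4 passed (GEM, ALDH1A3, the protocadherin PCDH17 and 1 without a symbol, named after their values were seen), at a median size of 0.67 and SE of 0.285. The number of calls was 259 without Noggin+DMSO replicate 3, 460 without Tris+DMSO replicate 1, 489 without Noggin+DMSO replicate 2, 534 without Noggin+DMSO replicate 1 and 536 without Tris+DMSO replicate 2. Of the 24 named genes 13 kept their call whichever single array was left out: ALDH1A3, FOXD1, GATA3, GEM, HSPH1, HTR1E, ID1, MECOM, PCDH10, PRRX1, RSPO3, SOHO1 and TCF21. The red blood cell list lost its call without Tris+DMSO replicate 3 (adjusted p = 0.0781, median 0.363) and the white blood cell list without Noggin+DMSO replicate 3 (0.112), Tris+DMSO replicate 2 (0.185) or the filter (0.0789), with a median of 0.255 without Tris+DMSO replicate 1. Without both arrays at the ends of the first principal component, chosen after seeing the data, the white blood cell list had a median of 0.258 (adjusted p = 0.146).

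**Figure D3:**
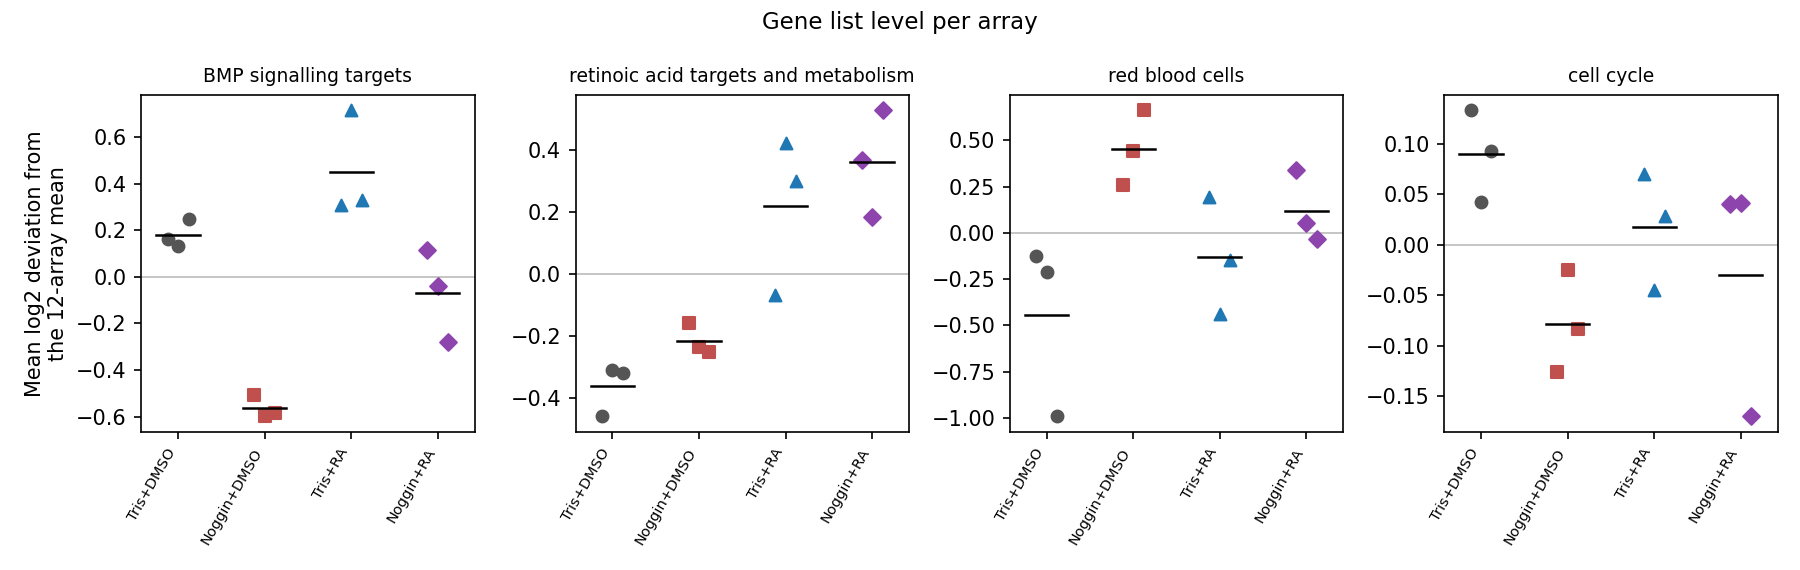
Mean log2 deviation of a gene list from its mean over the 12 arrays, for BMP signalling targets, retinoic acid targets and metabolism, red blood cells and cell cycle, points for arrays and lines for group means. BMP targets lay at 0.181 in Tris+DMSO, -0.563 in Noggin+DMSO, 0.45 in Tris+RA and -0.0681 in Noggin+RA.

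Genes changed by Noggin alone and by both factors overlapped. Of the probe sets changed in Noggin+RA, 66 rose in both comparisons and 45 fell in both, with 0 in opposite directions. TBX22, RSPO3, GEM, LHX8, MECOM and HSPH1 were among them. Both comparisons use the same control arrays, which alone makes their effects alike. Across probe sets the effects correlated at 0.684, against a mean of 0.497 in 20 simulations that kept this sharing but had no effect, and their covariance was 0.07 against 0.0183.

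Noggin in the presence of RA was tested as Noggin+RA against Tris+RA. RSPO3 rose 4.35-fold (log2 2.12, adjusted p = 0.00295), from 235 ± 62.0 to 1079 ± 299.8, and TBX22 3.64-fold (adjusted p = 0.00295), from 70.7 ± 7.35 to 299.9 ± 36.3. POSTN, the matrix protein periostin, rose 3.90-fold, PLAU 3.47-fold and NKX3-2 at least 2.88-fold, and GEM was at least 2.60-fold higher. ALDH1A2, the main RA-producing enzyme of the early embryo, was 2.24-fold lower (1219 ± 66.6 to 543 ± 123, adjusted p = 0.0282). BMP5, a BMP ligand, was 2.05-fold lower (181 ± 49.2 to 78.7 ± 8.48, adjusted p = 0.048). SEMA3D, a secreted guidance protein, was 1.84-fold lower, APOPT1, a mitochondrial protein, 1.71-fold, and UBA2, a subunit of the SUMO-activating enzyme, 1.59-fold. CDKN2B, a cell cycle inhibitor, was at least 1.35-fold lower. In this comparison 46 probe sets changed, 35 up and 11 down, for 33 genes and 8 probe sets without a symbol.

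BMP targets were the 1 list of 21 called for Noggin with RA present (median of 14 genes -0.468, camera adjusted p = 8.71e-08; adjusted p = 0.177 with an estimated correlation). Of its members 0 had a positive log2 value, 7 fell adjusted over the list alone and 0 over all probe sets. ID1 was at 2039 ± 180.4 in Tris+RA and 1352 ± 287 in Noggin+RA, and MSX2 at 215 ± 131 and 79.2 ± 22.6 (adjusted p = 0.185). Non-overlapping values were seen for 21.1% of probe sets (10% by chance). Rises made up 76.1% of calls here, 64.3% after quantile normalization and 59.5% after median centring. The GAPDH ratio as a covariate left 0 calls in limma and a fit of only the groups compared left 1 (TBX22, named after its value was seen), while an adjusted p below 0.10 gave 118. The count was 12 without Tris+RA replicate 2, 12 without Tris+RA replicate 3, 13 without Noggin+RA replicate 3, 15 without Noggin+RA replicate 2 and 27 without Tris+RA replicate 1. RSPO3 and TBX22 were the 2 of 12 named genes that kept their call whichever single array was left out.

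RA in the presence of Noggin was tested as Noggin+RA against Noggin+DMSO. CYP26A1 rose 10.6-fold (log2 3.40, SE 0.570, adjusted p = 0.0315), from 69.1 ± 10.9 to 998 ± 522, and PENK 6.21-fold (adjusted p = 0.00378). ALX1 rose 3.63-fold, from 258 ± 65.6 to 999.9 ± 340.2 (adjusted p = 0.0313), and was the 1 frontonasal factor of 11 that did. DLX5, DLX6 and ALDH1A3, which Noggin alone had raised, were lower with RA added. DLX5 was 4.33-fold lower (1921 ± 133 to 450.0 ± 165, adjusted p = 0.00331), DLX6 at least 3.37-fold lower (188 ± 26.8 to 28.3 ± 24.3, adjusted p = 0.0358), and ALDH1A3 5.35-fold lower (1353 ± 342 to 239.8 ± 59.1, adjusted p = 0.0313). DHRS3 (3.69-fold), CYP26C1, another RA-degrading enzyme (3.36-fold), and PLAU (2.95-fold) also rose. BNC1, a zinc finger factor of epithelia, was 3.39-fold lower, F13A1, a coagulation factor chain, at least 2.06-fold, and NR2E1, an orphan nuclear receptor, at least 1.37-fold.

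The retinoic acid list was higher with RA added to Noggin (median of 16 genes 0.475, camera adjusted p = 3.58e-06; adjusted p = 0.107 with an estimated correlation). CYP26A1, DHRS3, CYP26C1 and CRABP1, an RA-binding protein, rose and ALDH1A3 fell, with 10 rises and 1 fall adjusted over the list alone. BMP targets were higher in the group with RA (median of 14 genes 0.543, adjusted p = 5.95e-06; adjusted p = 0.156 with an estimated correlation). GATA3 (at least 2.31-fold, 40.8 ± 8.35 to 125 ± 23.9) and ID1 (2.40-fold, 545 ± 32.5 to 1352 ± 287) rose and 0 fell, with 7 rises adjusted over the list alone. White blood cell genes were lower (median of 9 genes -0.485, adjusted p = 3.58e-06; adjusted p = 0.156 with an estimated correlation). Over all probe sets 0 of them passed the test, and 6 were lower adjusted over the list alone, CSF1R and LCP1 among them. These 3 list calls held whichever single array was left out. Without the filter the medians of the retinoic acid list and BMP targets were 0.312 (adjusted p = 0.000146) and 0.215 (7.73e-05). The matrix link protein HAPLN1 (2.77-fold, 161 ± 18.8 to 474 ± 66.6) and the homeobox genes PITX1 (2.19-fold) and PRRX2 (2.01-fold) rose as list members.

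Changed by RA with Noggin present were 95 probe sets, 49 up and 46 down, for 73 genes and 21 probe sets without a symbol. Values that did not overlap were seen for 16.99% of probe sets (10% by chance). Of the 61 also changed by Noggin alone, 60 went the opposite way and 1 the same way. These comparisons share the Noggin+DMSO arrays, which enter them with opposite sign and so pull their effects apart. Across probe sets the effects correlated at -0.597, against a mean of -0.504 in simulations that kept this sharing but had no effect, and their covariance was -0.0555 against -0.0186. The GAPDH ratio as a covariate left 1 call (HAPLN1, named after its value was seen), and an adjusted p below 0.10 gave 196. The count was 25 without Noggin+DMSO replicate 2, 26 without Noggin+DMSO replicate 3, 28 without Noggin+RA replicate 1, 41 without Noggin+DMSO replicate 1, 49 without Noggin+RA replicate 3 and 58 without Noggin+RA replicate 2. BNC1, DLX5 and PENK were the 3 of 12 named genes that kept their call whichever single array was left out.

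The interaction asked whether the effect of RA differed with and without Noggin. With limma, 0 probe sets passed the test, and 1274 had an unadjusted p below 0.05 where chance gives 1068. SEMA3D had the smallest adjusted p, 0.125, at 253 ± 11.2 in the control, 357 ± 11.6 with Noggin, 310.2 ± 28.1 with RA and 162 ± 30.1 with both (log2 -1.35, SE 0.183). For ID1 the interaction was log2 1.19 (SE 0.218, adjusted p = 0.248), and for HAPLN1 it was 1.09 (SE 0.171, adjusted p = 0.196). It was -2.38 for ALDH1A3 (SE 0.570, adjusted p = 0.479) and -1.27 for DLX5 (SE 0.300, adjusted p = 0.473). Changes of 2-fold in this contrast were recovered in 39.6% of simulated cases. Without Noggin+RA replicate 1 there was 1 call, KAT2B, a histone acetyltransferase (log2 -2.33), named after its value was seen.

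Averaged over both Noggin states, RA raised genes of its own turnover. CYP26A1 rose 9.75-fold (SE 0.403 on log2, adjusted p = 0.00535), DHRS3 3.996-fold (SE 0.222, adjusted p = 0.00404) and CYP26B1 3.03-fold (SE 0.307, adjusted p = 0.0384). PENK rose 5.36-fold (SE 0.198, adjusted p = 0.00114), from 581 to 2842 with Tris and from 370.3 to 2462 with Noggin. DLX6 and DLX5 were at least 1.74-fold and 2.78-fold lower. FBXO32, a ubiquitin ligase subunit of muscle breakdown, rose 3.85-fold and CHGA, a granin of neuroendocrine cells, 3.16-fold. COL23A1, a membrane collagen, was 2.45-fold lower, SOCS2 2.36-fold, LRRC17, a leucine-rich repeat protein, 2.31-fold, and F13A1 at least 1.60-fold. In this average 175 probe sets changed, 99 up and 76 down, for 122 genes and 45 probe sets without a symbol.

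The retinoic acid list rose in the average effect of RA (median 0.287, camera adjusted p = 7.45e-08; adjusted p = 0.0465 with an estimated correlation). Of its 16 members 6 rose and 0 fell, with 8 rises and 1 fall adjusted over the list alone. BMP targets were higher (median 0.383, adjusted p = 6.9e-06; adjusted p = 0.0987 with an estimated correlation), with GATA3, BAMBI, ID1 and SMAD6 up and 5 up adjusted over the list alone. HOX genes were higher (median 0.368, adjusted p = 0.0122; adjusted p = 0.195 with an estimated correlation), with 0 past the test and 2 adjusted over the list alone. Skeletal muscle genes were higher (median 0.147, adjusted p = 0.0175; adjusted p = 0.0987 with an estimated correlation), with the contractile genes MYL4 and TNNC1 up and 3 up and 1 down adjusted over the list alone. Genes of neurons and cranial ganglia were higher (median 0.277, adjusted p = 0.018; adjusted p = 0.524 with an estimated correlation), with 0 past either test. White blood cell genes were lower (median -0.272, adjusted p = 8.83e-06; adjusted p = 0.128 with an estimated correlation), with 0 past the test and 4 adjusted over the list alone. The WNT list was lower (median -0.124, adjusted p = 0.0214; adjusted p = 0.0987 with an estimated correlation), with SFRP1 past the test adjusted over the list alone and 0 over all probe sets. Maxillary factors were lower (median -0.135, adjusted p = 0.0259; adjusted p = 0.279 with an estimated correlation). Among them PITX1 and PRRX2 rose and DLX5 and DLX6 fell, with 3 rises and 8 falls adjusted over the list alone.

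The count for the average effect of RA was 51 without Tris+RA replicate 3, 59 without Noggin+DMSO replicate 3 or Noggin+RA replicate 1, 64 without Tris+RA replicate 2, 70 without Noggin+DMSO replicate 2 and 85 without Tris+DMSO replicate 2. It was 96 without Noggin+DMSO replicate 1, Noggin+RA replicate 3 or Tris+DMSO replicate 3, and 46 with the GAPDH ratio as a covariate. COL23A1, CYP26A1, DHRS3, DLX5 and PENK were the 5 of 12 named genes that kept their call whichever single array was left out. Without the filter the lists of HOX genes (median 0.0751, adjusted p = 0.0898), WNT (-0.09, 0.0667), muscle (0.0766, 0.0667) and neurons (0.0965, 0.0898) lost their call, and the medians of the retinoic acid list and BMP targets were 0.151 and 0.243 (adjusted p = 7.12e-06 for each). The WNT list lost it without Noggin+DMSO replicate 3 (adjusted p = 0.0628) and that of maxillary factors without Noggin+DMSO replicate 1 (0.0508) or Tris+DMSO replicate 2 (0.0754) or 3 (0.0662). That of neurons lost it without Noggin+RA replicate 2 (0.0555), Noggin+DMSO replicate 3 (0.0628), Tris+RA replicate 1 (0.0526) or Tris+DMSO replicate 3 (0.133, median 0.153), with a median of 0.473 without Tris+DMSO replicate 1 and, chosen after seeing the data, 0.435 without both arrays at the ends of the first principal component. The median of HOX genes was 0.617 without Tris+RA replicate 1 and 0.201 without Tris+RA replicate 2.

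Averaged over both RA states, Noggin raised ALDH1A3 4.18-fold, RSPO3 4.15-fold (adjusted p = 8.81e-05), PTGDS at least 3.38-fold, SCARA5 at least 3.23-fold and GEM at least 2.63-fold. BMP3, a BMP family member that opposes other BMPs, rose 3.47-fold (62.1 ± 10.6 to 266 ± 7.90 with DMSO and 48.5 ± 33.4 to 180.2 ± 74.6 with RA). ALDH1A2 was 2.34-fold lower (adjusted p = 0.000571), ID1 2.30-fold (adjusted p = 0.000314), MECOM 2.24-fold, LHX8 2.23-fold and GATA3 at least 2.16-fold. For ALDH1A3 and ID1 the average covers a larger estimated change without RA than with it, though neither passed the test of the interaction. RASD2, a small GTPase, fell (adjusted p = 0.0059) and lay below background on every array with Noggin, so its fold had no lower limit above 1. All 12 named genes kept their call whichever single array was left out. In this average 2400 probe sets changed, 1446 up and 954 down and 103 of them at least 2-fold, for 1672 genes and 553 probe sets without a symbol.

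BMP targets fell in the average effect of Noggin (median of 14 genes -0.728, camera adjusted p = 1.09e-07; adjusted p = 0.183 with an estimated correlation), with 9 down, 0 up and 11 down adjusted over the list alone. Cell cycle genes were lower (median of 21 genes -0.117, adjusted p = 0.0122; adjusted p = 0.493 with an estimated correlation). The size of this fall depended on the scaling, with a median of -0.0595 after quantile normalization and -0.208 after median centring. MCM6, a DNA helicase subunit, and BUB1B, a mitotic checkpoint kinase, fell over all probe sets and over the list alone, and without Noggin+RA replicate 3 the median was -0.074. Red blood cell genes were higher (median of 8 genes 0.436, adjusted p = 0.0172; adjusted p = 0.493 with an estimated correlation). SLC4A1, HEMGN and TAL1 rose over all probe sets and adjusted over the list alone, and the call of the list was lost without Tris+DMSO replicate 3 (adjusted p = 0.0734, median 0.269).

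Rises made up 60.2% of the calls of the average Noggin effect here, 42.3% after quantile normalization and 28.2% after median centring. With the GAPDH ratio as a covariate 0 passed in limma, as the median SE of the 2400 went from 0.103 to 0.268 and the median size of their log2 change from 0.452 to 0.404. The count was 1078 without Noggin+RA replicate 3, 1111 without Noggin+DMSO replicate 3, 1343 without Tris+RA replicate 3, 1393 without Tris+RA replicate 2, 1483 without Tris+DMSO replicate 1 and 1547 without Noggin+DMSO replicate 1.

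Responses were finally compared across genes, with contrasts that share no arrays; probe sets are not independent replicates, so no p is given. The Noggin effects without and with RA had a Pearson correlation of 0.534 and a Spearman correlation of 0.542. The same sign in both was seen for 963 of the 1058 probe sets changed by Noggin alone and 42 of the 46 changed by Noggin with RA. Both contrasts also carry like differences between arrays. With Noggin the mean GAPDH ratio went from 0.824 to 0.669 without RA and from 0.807 to 0.721 with RA. Mean median intensity went from 37.5 to 44.2 and from 36.6 to 41.4. Alike Noggin responses and a shared difference in RNA quality or background cannot be told apart here. The slope of the Noggin effect with RA on that without RA, corrected for error, was 0.577 (jackknife SE 0.147). Such a slope falls with the correlation and is not a ratio of effect sizes. For RA the correlation of the effects without and with Noggin was 0.2004 by Pearson and 0.130 by Spearman. The slope of the effect with Noggin on that without, corrected for error, was 0.815 (jackknife SE 0.393). The SD of the RA effect over probe sets, error included, was 0.227 without Noggin and 0.263 with it. Of the 95 probe sets changed by RA with Noggin, 83 had the same sign with RA alone, those of CYP26A1, PENK, DHRS3, ALX1 and DLX5 among them. That Pearson correlation was 0.110 without Tris+RA replicate 2 and ran to 0.259 without Tris+RA replicate 1.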

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

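The tests of possible causes in this part, and the fits with a covariate, were chosen only after the results were seen; the interaction test of the lists and the count over splits of the arrays were planned.

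In the test of the difference itself, 3 lists passed for a difference of the RA effect between the groups with and without Noggin. Chance cannot be excluded, and 47 of 100 splits of the arrays gave as many lists. The splits shuffled both factors at once, so the effects of Noggin and RA enter them and the share does not measure chance alone. The 3 lists were cell cycle (median 0.141, adjusted p = 0.0258), red blood cells (median -0.522, adjusted p = 0.0119) and white blood cells (median -0.389, adjusted p = 0.0119). Each had an adjusted p = 0.648 with an estimated correlation, and 0 members passed over all probe sets or adjusted over the list alone. Without both arrays at the ends of the first principal component, a setting chosen after seeing the data, the medians of cell cycle and white blood cells were 0.0834 and -0.219 (adjusted p = 0.122 for each). The white blood cell call was lost without Noggin+RA replicate 3 (adjusted p = 0.0773), Noggin+DMSO replicate 3 (0.0792, median -0.253) or Tris+DMSO replicate 2 (0.0974). The red blood cell call was lost without Noggin+RA replicate 3 (0.0568), Noggin+DMSO replicate 3 (0.0661), Tris+RA replicate 1 (0.0739, median -0.286) or Tris+DMSO replicate 3 (0.392, median -0.188). The cell cycle call was lost without Noggin+RA replicate 1 (0.3) or 2 (0.166), Noggin+DMSO replicate 1 (0.125) or 3 (0.0661), Tris+RA replicate 2 (0.134) or Tris+DMSO replicate 1 (0.101) or 3 (0.051).

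Probe sets for avian viruses, left out of the comparisons, had a median intensity of 6.63 in Noggin+DMSO and 6.08 in Noggin+RA, above the 4.99 of Tris+DMSO and the 4.76 of Tris+RA.

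Noggin changed 2400 probe sets on average, with more rises than falls, while the GAPDH ratio, the median intensity and the mean of the red blood cell genes also differed. After quantile normalization 1944 were called, 823 up and 1121 down, where 1446 rose and 954 fell before. A change of scaling can trade rises for falls, so a similar total cannot decide whether scaling gave the number. Of the 1944, 1562 were among the 2400. Those calls did not hinge on the choice between these scalings, and the others did. For the excess of rises scaling and Noggin cannot be told apart: the share went from 60.2% to 42.3%, but quantile normalization itself sets the balance of rises and falls. Within groups, the slope of each probe set on the GAPDH ratio predicted a share of 0.043 (SE 0.202) of the Noggin effect, the slope on the mean of SLC4A1, HEMGN and TAL1 a share of -0.0274 (SE 0.133), and that on all 8 red blood cell genes -0.0257 (SE 0.086). The values for blood argued against blood content as the main cause. For 3' bias the slope cannot decide. The SD of the GAPDH ratio within a group was 0.0139 to 0.0440, beside a difference of -0.12 between Noggin and Tris arrays. Error in so small a spread pulls the slope towards 0. With the GAPDH ratio as a covariate 0 calls were left as the median SE went from 0.103 to 0.268, so 3' bias and Noggin cannot be told apart. With the mean of SLC4A1, HEMGN and TAL1 as a covariate 98 calls were left, at a median SE of 0.186. An effect of Noggin on these genes stays open, not tested apart from these measures.

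Red blood cell genes were higher in Noggin+DMSO than in the control by a median of 0.697, a call lost with an estimated correlation (adjusted p = 0.619). The median of 0.677 after quantile normalization argued against scaling as the cause. A difference in the blood content of the pools may account for it: the 8 genes moved together within groups, with a mean residual correlation of 0.582 where the highest of 10000 random lists gave 0.38. The globin genes HBBR and HBAD, at 5200 and 5665 against 3342 and 3676, went the same way. Whether Noggin changed the blood in the tissue or the dissection did stays untested, and without Tris+DMSO replicate 3, whose list mean was -0.991 beside -0.123 and -0.213 in its group, the median was 0.363 (adjusted p = 0.0781).

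BMP targets were higher with RA added to Noggin by a median of 0.543, a call lost with an estimated correlation (adjusted p = 0.156). The largest adjusted p of the list over the arrays left out, 0.000268, argued against 1 array as the source, while the size depended on the filter, since without it the median was 0.215 (adjusted p = 7.73e-05). A smaller Noggin effect on genes in general in the presence of RA could account for a part of it: the ratio of the Noggin effect with RA to that without was 0.697 (SE 0.28) for the 14 targets and 0.71 (SE 0.107) for the 2391 other probe sets changed by Noggin, a difference of -0.0126 (SE 0.231). It cannot give the rise with RA where no Noggin was present: the mean of the list was 0.306 to 0.714 on the Tris+RA arrays and 0.133 to 0.246 in the control (median difference 0.108, adjusted p = 0.0215; 0.36 with an estimated correlation). That call was lost without Tris+RA replicate 2 (camera adjusted p = 0.102) or Tris+DMSO replicate 2 (0.0551). The interaction of the list had a median of 0.285 and an adjusted p of 0.0733 (0.648 with an estimated correlation), and how the causes add up stays open.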

How the results depend on the processing

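Settings were planned except the fits with a covariate and without both arrays at the ends of the first principal component, which were chosen after seeing the data. Counts of changed probe sets are given for both factors together (173), RA alone (0), Noggin alone (1058), Noggin with RA present (46), RA with Noggin present (95), the interaction (0), the average RA effect (175) and the average Noggin effect (2400); counts within 1.5 times these are left out. The cause of each shift was not tested unless stated.

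Quantile normalization gave 28 for Noggin with RA present and a correlation of the Noggin effects of 0.502, and median centring 2 for RA alone (PENK and 1 probe set without a symbol, named after their values were seen). Without a filter, where more probe sets were tested, the counts were 63 for both factors, 676 for Noggin alone, 16 for Noggin with RA, 45 for RA with Noggin and 80 for the average RA effect, and the correlations were 0.130 for RA and 0.416 for Noggin. With a filter at the 70th percentile, where fewer were tested, they were 316 for both factors, 7 for RA alone and 2 for the interaction (SEMA3D and HECW1, log2 -1.35 and -1.11, named after their values were seen), and the correlations 0.287 and 0.636. A trended and robust prior gave 311 for both factors, 8 for RA alone and 80 for Noggin with RA, and array weights gave 185 for RA with Noggin. A pseudocount of 1 gave 18 for Noggin with RA and 51 for RA with Noggin. A pseudocount of 64 gave 305 for both factors, 10 for RA alone, 72 for Noggin with RA, 155 for RA with Noggin and 1 for the interaction (SEMA3D). A fit of only the groups compared, with fewer arrays behind the spread, gave 4 for both factors, 531 for Noggin alone, 1 for Noggin with RA and 32 for RA with Noggin. A minimum fold of 1.5 left 591 for the average Noggin effect. An adjusted p below 0.10 gave 422 for both factors, 2 for RA alone (again PENK and 1 without a symbol), 2514 for Noggin alone, 118 for Noggin with RA, 196 for RA with Noggin, 298 for the average RA effect and 4487 for the average Noggin effect.

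A block for the replicate number gave 83 for both factors, 12 for Noggin with RA, 42 for RA with Noggin and 82 for the average RA effect. The numbers did not pair the arrays: residuals of arrays with the same number correlated at a median of -0.00872 (18 pairs) and those with different numbers at 0.0123 (36 pairs), and 1 of 12 arrays correlated best with one of its own number.

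Without both arrays at the ends of the first component, the counts were 52 for both factors, 136 for Noggin alone, 29 for Noggin with RA, 13 for RA with Noggin, 40 for the average RA effect and 663 for the average Noggin effect. The mean of SLC4A1, HEMGN and TAL1 as a covariate, which carries part of the Noggin contrast since these are the red blood cell genes that Noggin raised, gave 103 for both factors, 4 for Noggin alone, 10 for RA with Noggin, 108 for the average RA effect and 98 for the average Noggin effect. The GAPDH ratio as a covariate gave 2 for both factors, 0 for Noggin alone, 0 for Noggin with RA, 1 for RA with Noggin, 46 for the average RA effect and 0 for the average Noggin effect. Signs held for 2376 (mean of the 3 genes) and 2274 (GAPDH ratio) of the 2400.

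Leaving out 1 array gave counts from 33 to 117 for both factors, 0 to 21 for RA alone, 259 to 802 for Noggin alone, 12 to 37 for Noggin with RA, 25 to 58 for RA with Noggin, 0 to 1 for the interaction, 51 to 190 for the average RA effect and 1078 to 2324 for the average Noggin effect. Correlations then ran from 0.110 to 0.259 for RA and from 0.460 to 0.534 for Noggin.

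Of 1937 alternatives of the 96 named gene results, 1390 kept direction and call, 544 lost the call and 3 turned the direction. The 3 were SLC4A1 (log2 -0.33), TUBB1 (-0.85) and ANK1 (-0.10) for Noggin alone with the covariate of 3 red blood cell genes, of which SLC4A1 is itself a part. Leaving out 1 array in turn set aside, 6 of the 96 results kept their call under every alternative, covariate fits included. No named gene turned under quantile normalization or median centring. Of the 35 list calls, an estimated correlation kept 1, no filter 25, the mean of all probe sets of a gene 32, the replicate block 35 and the fit without both end arrays 27. The median of red blood cells for RA alone turned to -0.0265 without Tris+DMSO replicate 3 and was 0.455 without Tris+DMSO replicate 1. The mean share of chicken probe sets above background was 50.7% to 52.4% in the groups, and whether this limits the counts was not tested.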

Other observations

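The tests in this part were planned, except the look at the make-up of 1 split; which list members are described followed the results.

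The list of BMP ligands, receptors and antagonists had members that rose and members that fell with Noggin (camera adjusted p = 0.481 over 19 genes for Noggin alone). BMP3 rose 3.64-fold, BMPR1B, a type I receptor, 2.39-fold (196 ± 37.9 to 484 ± 21.6), BMP7 2.22-fold (261 ± 44.6 to 602 ± 126), GDF5, a ligand of joint formation, 1.46-fold, and BMP6 at least 1.41-fold. BMP5 was 2.16-fold lower (125 ± 25.8 to 48.7 ± 2.59). The same 5 rises and 1 fall passed adjusted over the list alone. With both factors 0 of the 19 passed over all probe sets, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.249).

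The WNT pathway list had 4 rises and 3 falls with Noggin alone (camera adjusted p = 0.465 over 22 genes; 5 rises and 3 falls adjusted over the list alone). Beside RSPO3, RSPO1, a WNT enhancer of the same family, rose 1.75-fold (50.7 ± 12.9 to 102 ± 27.9), and so did the WNT inhibitors NOTUM (1.87-fold) and DKK2 (1.52-fold). WIF1, FRZB (1.45-fold lower, 1622 ± 175 to 1111 ± 55.8) and WNT5A (1.495-fold lower, 1362 ± 93.1 to 906 ± 73.2) fell. With both factors RSPO3 and RSPO1 (2.23-fold) rose and FRZB was 1.69-fold lower.

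Enzymes that make RA moved apart with Noggin. ALDH1A3 rose while ALDH1A2 was 2.44-fold lower (772 ± 28.3 to 312 ± 70.3, adjusted p = 0.00341), and the retinoic acid list as a whole had a camera adjusted p of 0.875. In the average Noggin effect STRA6, the receptor that takes up retinol (log2 0.66, adjusted p = 0.0219), and RDH10, which makes retinaldehyde (log2 0.51, adjusted p = 0.0497), rose too. Of the FGF list IL17RD, an inhibitor of FGF signalling, was 1.60-fold lower with Noggin alone (camera adjusted p = 0.102 over 16 genes; 1 up and 5 down adjusted over the list alone). Of the apoptosis list 0 of 18 passed and GADD45G rose adjusted over the list alone (camera adjusted p = 0.875). VWF, a marker of endothelium, rose by 0.66 on the log2 scale as the 1 of 16, over all probe sets and over the list alone (camera adjusted p = 0.289). For neural crest glia (0 of 6 passed, 1 down adjusted over the list alone) and lens (0 of 9 by either count) the camera adjusted p was 0.258 and 0.875.

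Other splits of the same arrays were fitted in the same way. For the pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 with the most calls for both factors (173, highest other 0), Noggin alone (1058, highest other 1), Noggin with RA (46, highest other 1) and RA with Noggin (95, highest other 1). For RA alone all 10 splits gave 0 (real 0, highest other 0). Of 100 drawn splits of the 12 arrays, the real one included, 1 gave as many calls as the average RA effect (175, highest other 18) and 1 as the average Noggin effect (2400, highest other 250), so chance is unlikely for both. The same holds for the number of lists called in the average RA effect (8, 1 split, highest other 6). It does not speak for each of the 8 lists, as another split called 6. It also holds for the correlation of the Noggin effects (1 split, highest other 0.385). For the correlation of the RA effects (0.2004) 2 splits, the real one included, were as high. The other reached 0.229, above the real value, so chance is less clearly set aside there. Chance cannot be excluded for the number of lists called in the average Noggin effect (3, 37 splits, highest other 6) or the interaction (3, 47 splits, highest other 6). The interaction splits shuffled both factors at once, so that share does not measure chance alone. These counts do not weigh how far 1 list moved. The mean of the BMP targets was -0.599 to 0.114 on the Noggin arrays and 0.133 to 0.714 on the Tris arrays. Lists not called in the average Noggin effect were apart as well. BMP ligands, receptors and antagonists lay at -0.014 to 0.246 on the Noggin and -0.216 to -0.024 on the Tris arrays. The hedgehog list lay at 0.029 to 0.277 and -0.226 to -0.026. Such a separation is therefore not particular to the BMP targets, and it was not tested. For the interaction all 100 splits gave at least 0 calls, and the highest other gave 199, which points to a structure among the arrays. That split had 5 of the 6 Noggin arrays on the same side. Drawn splits with 3 or 4 Noggin arrays together gave at most 2 and 1 calls (36 and 51 splits). The 12 drawn splits with 5 together reached 199 but had a median of 0, and 1 drawn split gave more than 100 calls. Which structure it follows therefore stays open.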
